A study of Homo sapiens with 6 samples.

How the data were processed

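Tethered chromosome capture (TCC) is a form of Hi-C in which crosslinked chromatin is cut with a restriction enzyme, tethered to a solid surface and ligated there, so that sequences close together in the nucleus are joined and can be read as pairs. The 6 samples comprised 1 TCC library of MCF7, an estrogen receptor positive breast cancer cell line, 1 TCC library of PANC1, a cell line from a pancreatic ductal carcinoma, and 4 anti-CTCF ChIP-seq libraries of PANC1, which were not analysed here. Per the labels' protocols the nuclei were cut with HindIII. Groups were taken from the sample titles for the TCC libraries and from the antibody label for the ChIP-seq libraries. The growth description of the MCF7 library names PANC1 cells, while its title and cell line label name MCF7. The title was followed, and all comparisons between the cell lines rest on it.

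Each TCC library came as 1 list of intrachromosomal locus pairs with 7 columns per line and no header. From the values, these hold the chromosome number of each locus, the start and end of both loci, and 1 negative score per pair. Chromosomes were numbered 1 to 23, and the number 23 is kept here as the files give it. The submitters' processing notes name Bowtie 0.12.5 and the hg19 genome build. How the authors placed the loci, which pairs they kept and how they computed the deposited score are not given in the sources used here. The score was used to rank pairs within a list, to count pairs below -100 in both lists, and to order shared pairs by the weaker of their scores. A more negative score was taken as a stronger pair, which is an assumption made from the values. Whether scores of the same size mean the same in both lists is not known. The files give no read counts, so the sequencing depth is unknown and the number of listed pairs was used as the measure of each library. Coordinates are printed as the files give them. Loci were at most 5000 bases wide.

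The distance of a pair was taken between the midpoints of its loci. Pairs were assigned to distance bands with edges at 20 kb, 100 kb, 1 Mb and 10 Mb. A pair was called shared when both of its loci overlapped those of a pair in the other library by at least 1 base. The number of shared pairs was set beside 100 random placements, in which all PANC1 pairs of a chromosome were moved together around the covered span of that chromosome, so that distances and spacing were kept. The ends of pairs (locus midpoints) were counted in 1 Mb bins. A bin was ranked when it held at least 20 ends in 1 of the libraries. The ratio of a bin was the log2 of ends plus 0.5 in MCF7 over PANC1, each divided by the library's total of ends. A bin listed at 0 in one library was compared against a floor of 3 ends over that library. Runs of at least 3 adjacent bins with a 4-fold difference in the same direction were joined into regions, a step added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

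With 1 library per cell line there was no replicate, so no test between the cell lines was made and no p-value is given. Intervals are 95% intervals: exact binomial (Clopper-Pearson) for shares, exact Poisson for counts of ends, exact binomial conditional on the summed count for ratios, and a normal approximation for the difference of shares. They cover counting error only, and pairs that share a locus are not independent. Because a pair inside a bin gives both of its ends to it, intervals of bin counts and bin ratios are narrower than intervals over pairs would be. On simulated lists, 100.0% of 2000 planted shared pairs were recovered. Of 200 bins raised 8-fold in simulated counts, 92.5% came out at 4-fold or more, and 0 of 1981 unchanged bins did. The planted pairs were MCF7 pairs moved by a few bases, so their recovery checked the matching only. The simulated ends were drawn independently rather than as pairs, and the raised bins were chosen among well-filled ones. The simulated shares therefore do not cover the pairing of ends or sparse bins.

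The items named in the text were chosen before the data were examined by these rules. The 5 bins with the highest and the 5 with the lowest ratio among ranked bins were named, and from each library the 5 pairs with the strongest score, together with their ties. Other regions and pairs, including the runs of bins, were chosen after their values were seen. Alternatives fixed beforehand were the 0.5 of each list with the stronger scores, a minimum distance of 20 kb, each unordered pair counted once, other definitions of a shared pair, thinning of the MCF7 list to the PANC1 number, and bins of 500 kb and 2 Mb. Weighting by read counts could not be done, since the files hold none. The planned comparison of promoters and of 10 gene lists was not made, because the gene table used here gives positions on another build (GRCh38) than the pairs. No gene is therefore placed on a locus, and positions in exons, introns or promoters are not given.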

Results

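Contacts within chromosomes were mapped by TCC in 2 cancer cell lines, MCF7 from breast and PANC1 from pancreas, with 1 library each. The study set these maps beside histone modification and expression data to find loops between regulatory elements, and the comparison that the pair lists allow is between the cell lines. The MCF7 list held 126103 pairs and the PANC1 list 111237, a ratio of 1.13. The pairs joined 204058 distinct loci covering 544 Mb in MCF7 and 185129 loci covering 484 Mb in PANC1. Loci had a median width of 3651 bases in MCF7 and 3435 bases in PANC1. Most loci took part in a single pair, 83.7% of them in MCF7 and 84.3% in PANC1. A locus was counted by its exact start and end, so overlapping loci with other edges counted as different ones. Loci in 5 or more pairs numbered 1415 in MCF7 and 440 in PANC1. The median score was -9.74 in MCF7 and -9.33 in PANC1. There were no replicates, so none of the differences below could be set against a spread between libraries.

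The first comparison asked over what distances the listed contacts reached. Listed pairs were mostly short in both cell lines, and MCF7 held the larger share of long ones. The smallest gap between paired loci was 2 bases in MCF7 and 1 base in PANC1. The lists give no means to tell pairs of adjoining restriction fragments from contacts over a distance. The median distance was 17.9 kb in MCF7, with quartiles of 7.19 and 39.0 kb, and 16.9 kb in PANC1, with quartiles of 6.88 and 33.9 kb. Pairs under 20 kb made up 53.6% of the MCF7 list (95% interval 53.3 to 53.9) and 55.3% of the PANC1 list (54.98 to 55.56). Pairs of at least 100 kb made up 11.9% in MCF7 (11.7 to 12.1) and 8.53% in PANC1 (8.36 to 8.69), a difference of 3.35 percentage points (3.112 to 3.597). Of the 23 chromosomes, 15 had a higher share of such pairs in MCF7. The share was 32.0% on MCF7 chromosome 20 and 22.7% on MCF7 chromosome 17, against 7.17% and 8.41% on the same chromosomes of PANC1. PANC1 had the higher share on chromosome 19, with 20.2% against 7.21%.

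**Figure D1:**
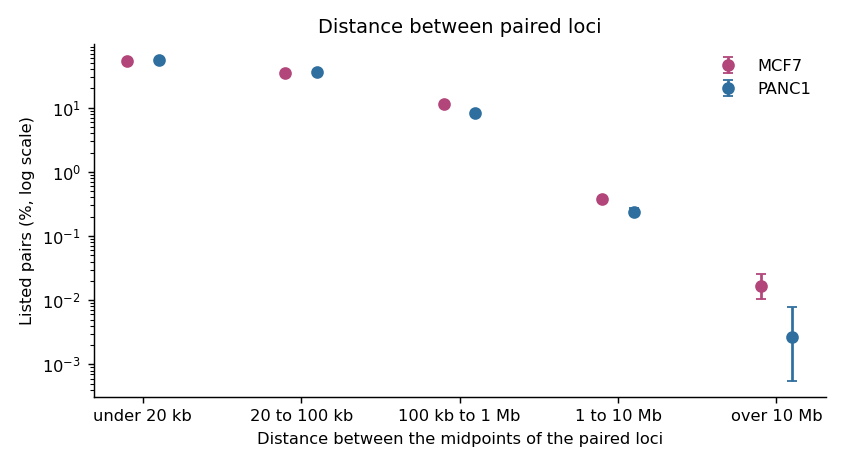
Share of listed pairs (percent, log axis) in 5 bands of distance between locus midpoints, for the MCF7 and PANC1 TCC libraries. Points are shares and bars are 95% exact binomial intervals, which cover counting error only; pairs of 100 kb to 1 Mb were 11.5% of the MCF7 list and 8.28% of the PANC1 list.

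The share of long pairs rose with the number of pairs around them. Among pairs whose first locus lay in a 1 Mb bin with up to 100 ends, 7.24% of MCF7 pairs and 6.31% of PANC1 pairs reached at least 100 kb. In the 32 MCF7 bins with more than 500 ends the share was 39.0% (38.2 to 39.9), and in the 13 such bins of PANC1 it was 16.4% (15.3 to 17.6). Leaving out those bins, an alternative chosen after the data were seen, brought the shares to 8.89% in MCF7 and 8.24% in PANC1. Each library lost its own bins, so the parts of the genome left out differed between the cell lines. The difference between the cell lines then fell from 3.35 to 0.65 percentage points.

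Most contacts of at least 2 Mb lay on chromosome 20 of MCF7. Pairs at least 2 Mb apart numbered 290 in MCF7 and 26 in PANC1. Of the 290, 245 (84.5%) were on chromosome 20, which held 4.32% of all MCF7 pairs. They joined a few separate places on the long arm. Between the bins at 52 and 55 Mb there were 145 pairs, from loci between 52178731 and 52927618 to loci between 55680226 and 55854638. Another 35 pairs joined the bins at 45 and 49 Mb, 15 joined 46 and 52 Mb, 13 joined 46 and 49 Mb, and 10 joined 41 and 52 Mb. A further 8 pairs led from the bin at 45 Mb to loci between 55684084 and 55839194. The 26 PANC1 pairs were spread over many chromosomes, with at most 4 on any of them.

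**Figure D2:**
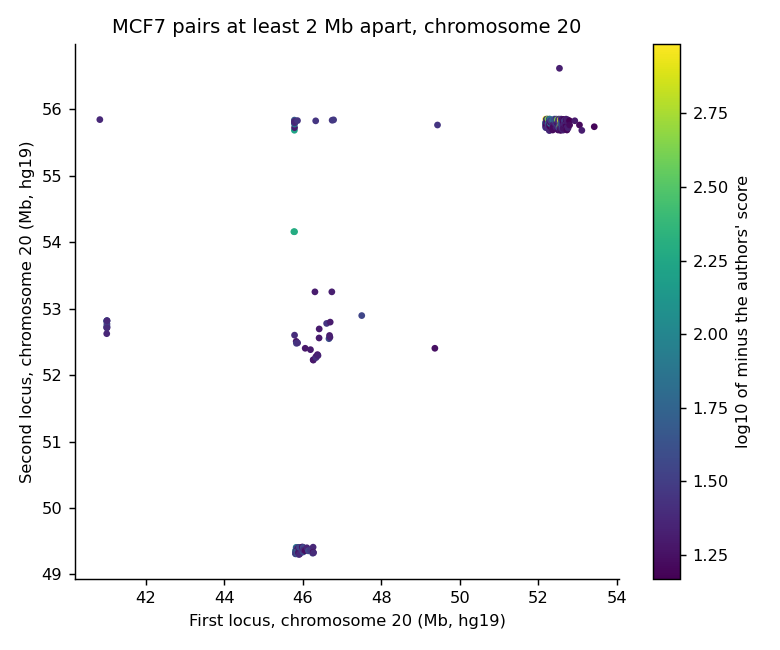
MCF7 pairs at least 2 Mb apart on chromosome 20 (hg19), each point 1 pair, with the position of the first locus on the x axis and of the second on the y axis, both in Mb. Colour gives log10 of minus the authors' score; the 145 pairs between 52 and 55 Mb form the cluster at the upper right.

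The pairs with the strongest scores sat in a few regions that differed between the cell lines. In MCF7, 3 pairs tied at a score of -17703, all on chromosome 20, at 52743970-52745900 with 52748192-52749629, at 53028042-53031771 with 53034784-53036335, and at 53133871-53136377 with 53139722-53143654. Another 3 tied at -13913 on chromosome 17, at 59569970-59572596 with 59594419-59596835, at 59687513-59688013 with 59690909-59691409, and at 59712928-59717928 with 59724821-59729821. In PANC1, 5 pairs tied at -520 on chromosome 19. They lay between 40225994 and 40273458, and the locus at 40271016-40272337 took part in 3 of them. Its partners included the overlapping loci 40272659-40273311 and 40272659-40273458. The strongest pairs were short, from 1.31 to 24.3 kb. Of the 441 MCF7 pairs with a score below -100, 147 were on chromosome 3, 115 on chromosome 20, 103 on chromosome 17 and 70 on chromosome 1. Of the 28 such pairs in PANC1, 24 were on chromosome 19. In the bin at 40 to 41 Mb of chromosome 19, PANC1 had 502 ends and MCF7 12, a 47.4-fold higher share in PANC1 (26.9 to 92.4).

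The loci joined to the most partners lay mostly on the same chromosomes as the strongest scores. In MCF7 the locus at 52566991-52571991 of chromosome 20 took part in 30 pairs, that at 60189211-60190889 of chromosome 17 in 23, and that at 61841450-61843863 of chromosome 3 in 19. In PANC1 the largest numbers were 13 pairs at 40161740-40163962 and 12 at 40273471-40277725, both on chromosome 19, and 10 at 83184483-83188481 on chromosome 1. Loci in 8 or more pairs numbered 329 in MCF7, of which 144 were on chromosome 3 and 89 on chromosome 20. In PANC1 there were 22, of which 10 were on chromosome 1 and 7 on chromosome 19.

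Whole chromosomes differed in their share of the pairs. Chromosomes 20, 17, 16, 14, 22 and 9 each had an at least 2-fold higher share in MCF7. Chromosome 20 held 4.32% of MCF7 pairs and 0.953% of PANC1 pairs, a ratio of 4.54 (4.25 to 4.85). The ratio was 4.18 (3.90 to 4.48) for chromosome 17, 3.65 (3.31 to 4.03) for chromosome 16 and 3.46 (3.27 to 3.67) for chromosome 14. Chromosomes 11, 19 and 18 had an at least 2-fold higher share in PANC1. Chromosome 11 held 6.69% of PANC1 pairs and 1.92% of MCF7 pairs, 3.48-fold higher in PANC1 (3.33 to 3.65). The share was 2.83-fold higher in PANC1 (2.42 to 3.32) for chromosome 19 and 2.54-fold higher (2.34 to 2.76) for chromosome 18. The intervals of the cell lines did not overlap for 20 of the 23 chromosomes. Chromosome 22 was sparse in both lists, with 99 pairs in MCF7 and 27 in PANC1. Chromosome 3 held the most pairs in MCF7, 18376, and chromosome 6 the most in PANC1, 12855.

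Along the chromosomes these differences were uneven. Of 2273 ranked 1 Mb bins, 342 (15.05%, 13.6 to 16.6) had an at least 4-fold higher share of ends in MCF7 and 193 (8.49%, 7.38 to 9.71) in PANC1, while 49.9% were within 2-fold. The highest MCF7 to PANC1 ratios were on chromosomes 17, 20 and 1. The bin at 58 to 59 Mb of chromosome 17 had 679 ends in MCF7 (629 to 732) and was listed at 0 in PANC1, at least 200-fold higher in MCF7. The adjacent bin at 57 to 58 Mb had 402 ends against 0, at least 118-fold higher. The bin at 47 to 48 Mb of chromosome 20 had 210 against 0, at least 61.7-fold higher. On chromosome 1, the bin at 114 to 115 Mb had 718 ends against 2, a ratio of 317 (87.3 to 2620), and the bin at 203 to 204 Mb had 85 against 0, at least 24.99-fold higher.

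The lowest ratios were on chromosomes 11 and 6. The bin at 99 to 100 Mb of chromosome 11 had 351 ends in PANC1 and 2 in MCF7, 199-fold higher in PANC1 (54.7 to 1649). On the same chromosome the bins at 114 to 115 Mb and at 51 to 52 Mb had 65 and 56 ends in PANC1 and were listed at 0 in MCF7, at least 24.6-fold and at least 21.2-fold higher. With 2 Mb bins, which add the bin before it, the log2 ratio at 51 Mb went from -7.00 to -0.87, below 4-fold. On chromosome 6 the bins at 167 to 168 Mb and at 169 to 170 Mb had 42 and 37 ends in PANC1 and were listed at 0 in MCF7, at least 15.9-fold and at least 13.98-fold higher.

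**Figure D3:**
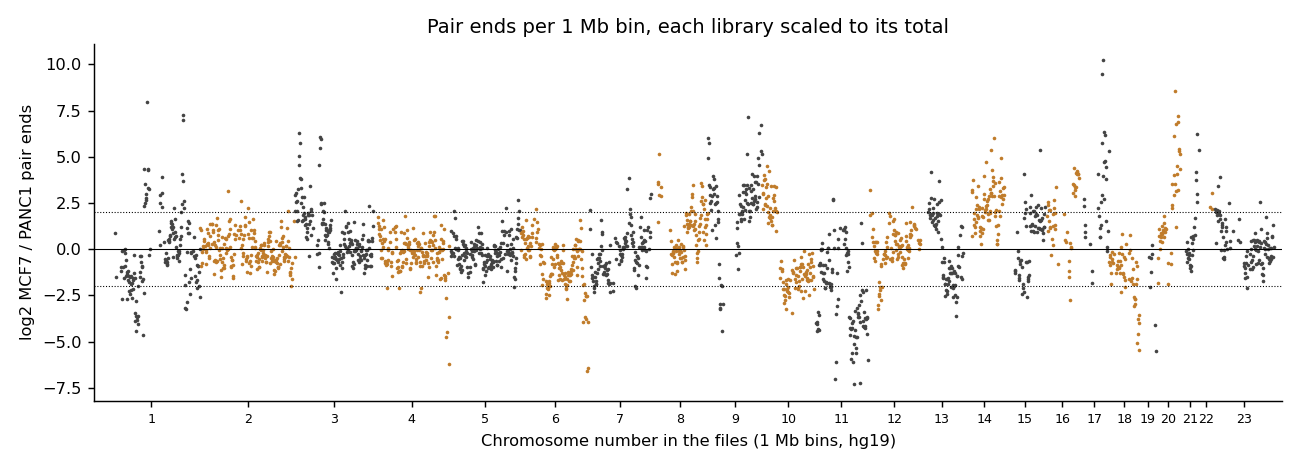
Log2 ratio of pair ends in MCF7 over PANC1 in each ranked 1 Mb bin, each library scaled to its total, with chromosomes side by side in alternating colours and dotted lines at 4-fold. Points above 2 (342 bins) and below -2 (193 bins) gather in runs of neighbouring bins.

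Many of these bins were neighbours. Runs of at least 3 adjacent bins numbered 30 in the MCF7 direction and held 230 of its 342 bins, and 17 in the PANC1 direction, with 118 of its 193 bins. The regions of MCF7 with the most ends were 61 to 67 Mb of chromosome 3, 54 to 67 Mb of chromosome 17 and 52 to 61 Mb of chromosome 20. The chromosome 3 region held 5860 ends in MCF7 and 128 in PANC1, a ratio of 40.4 (33.9 to 48.5). Its last bins, at 65 to 66 and 66 to 67 Mb, held only 88 and 68 of the MCF7 ends. The ratio was 18.3 (16.3 to 20.7) for the chromosome 17 region and 22.9 (19.8 to 26.5) for the chromosome 20 region. A second region of chromosome 20, at 44 to 51 Mb, had a ratio of 33.5 (25.2 to 45.6). Chromosome 1 had MCF7 regions at 106 to 113 Mb, with a ratio of 10.7 (9.12 to 12.5), and at 114 to 119 Mb, with 23.2 (18.6 to 29.3). Long MCF7 regions also lay at 106 to 130 Mb of chromosome 9, 70 to 84 Mb of chromosome 16 and 0 to 15 Mb of chromosome 10, with ratios of 8.50, 13.0 and 8.59.

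The longest PANC1 region spanned 87 to 117 Mb of chromosome 11, with 6645 ends in PANC1 and 366 in MCF7, 20.6-fold higher in PANC1 (18.5 to 22.9). Beyond it, at 120 to 135 Mb, the share was 13.3-fold higher (10.7 to 16.6). A region at 83 to 93 Mb of chromosome 1 was 12.1-fold higher (10.9 to 13.4), one at 71 to 77 Mb of chromosome 18 was 20.5-fold higher (15.5 to 27.7), and one at 24 to 27 Mb of chromosome 12 was 7.33-fold higher (6.33 to 8.51). Chromosome 9 carried regions in both directions. At 29 to 32 Mb PANC1 was 8.92-fold higher (7.25 to 11.1), although the chromosome as a whole had a 2.74-fold higher share in MCF7 (2.58 to 2.92).

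**Figure D4:**
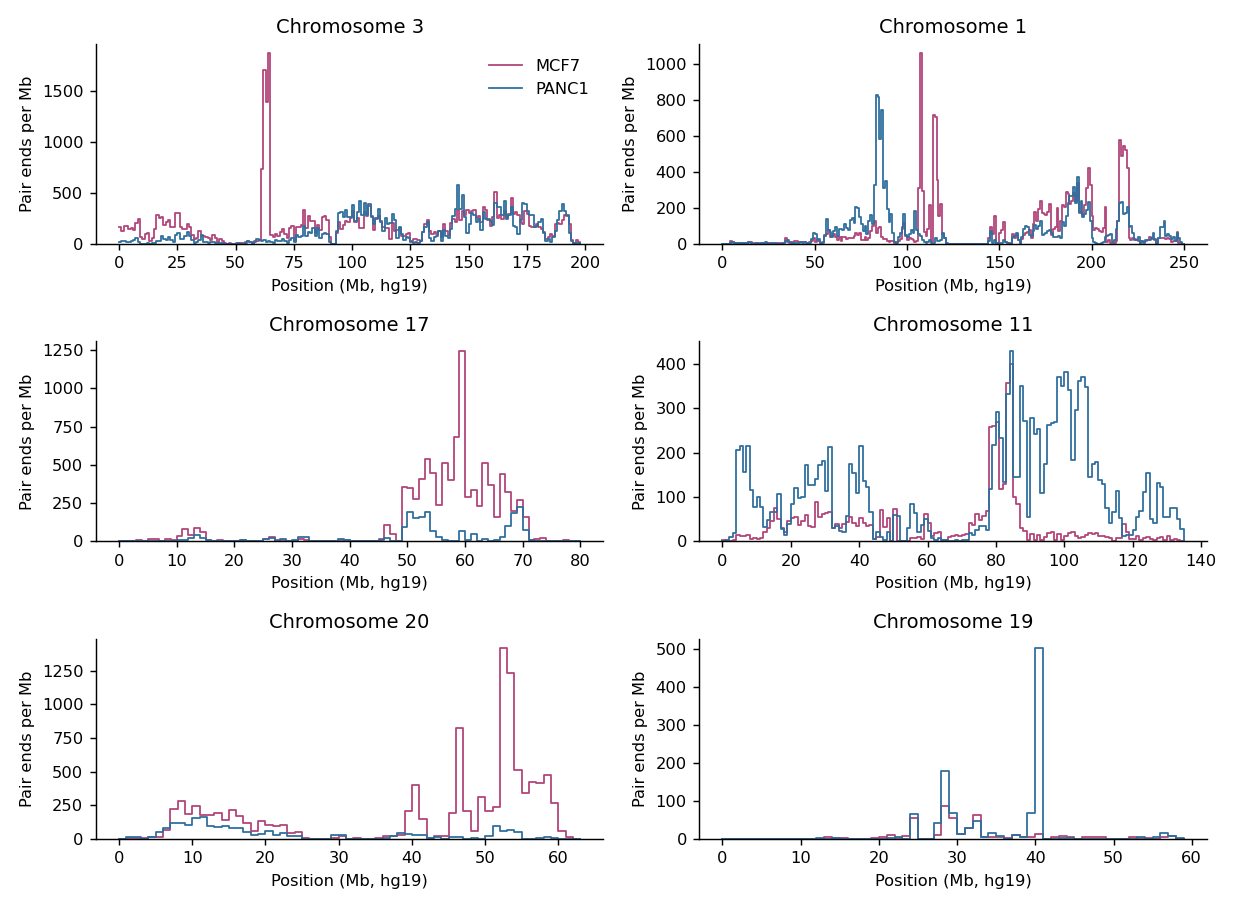
Pair ends per 1 Mb bin (y axis, linear, unscaled counts) along chromosomes 3, 17, 20, 1, 11 and 19 (x axis, position in Mb, hg19) in the MCF7 and PANC1 libraries. Peaks of MCF7 stand at 61 to 65 Mb of chromosome 3 and 52 to 61 Mb of chromosome 20. Peaks of PANC1 stand at 83 to 93 Mb of chromosome 1 and 40 to 41 Mb of chromosome 19.

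The last comparison asked how many contacts were listed in both cell lines. Of the MCF7 pairs, 8149 (6.46%, 6.33 to 6.60) overlapped a PANC1 pair at both loci, and 8133 PANC1 pairs (7.31%) overlapped an MCF7 pair. In 100 random placements the number of MCF7 pairs was 4037 ± 231 (SD over placements) and at most 4529, so the observed number was 2.02 times the random one and above all placements. Placements moved by only 100 kb to 1 Mb, chosen after the data were seen, gave 5536 on average and at most 5810, which left a ratio of 1.47. Both kinds of placement moved loci off the edges that the lists had in common, 75364 or 23.2% of the distinct PANC1 edges. The ratios therefore do not separate shared contacts from shared locus edges. Pairs with identical loci in both lists numbered 820, and 75341 MCF7 pairs (59.7%) had a PANC1 pair within 20 kb at both loci, 1.57 times the random number.

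Sharing depended on distance. Under 20 kb, 9.81% of MCF7 pairs were shared, 1.54 times the mean of the placements moved by 100 kb to 1 Mb. From 20 to 100 kb it was 3.34% and 1.20 times. From 100 kb to 1 Mb only 63 of 14484 pairs were shared (0.435%, 0.334 to 0.556), but the placements gave 11.2 on average and at most 23, so the excess was 5.61 times. From 1 to 10 Mb, 0 of 476 pairs were shared, and over 10 Mb 1 of 21 was. The shared pairs of 100 kb to 1 Mb were ranked by the weaker of the scores of the cell lines. The first was on chromosome 7, where 28962206-28965530 and 29146203-29149308 were paired with the same edges in both lists. Its score was -31.6 in MCF7 and -55.7 in PANC1. The second was also on chromosome 7, at 86570866-86572496 with 86774555-86777889 in MCF7, with scores of -31.2 and -34.6. A longer one, of 493 kb, joined 75274640-75278665 and 75767399-75772399 on chromosome 8 in MCF7, with scores of -26.2 and -59.5. These pairs were chosen after their values were seen. The shared percentage was highest on chromosome 6, at 10.8% of MCF7 pairs. It was 2.00% on chromosome 20, 1.53% on chromosome 9 and lowest on the sparse chromosome 22, at 1.01%. PANC1 had 12855 pairs on chromosome 6 to share with, but 1060 on chromosome 20 and 1321 on chromosome 9. No random number was computed per chromosome, so these percentages are not separated from the unequal numbers of pairs.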

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

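The log2 ratios of chromosomes 1, 13 and 23 changed sign in some settings, and their main intervals included a ratio of 1; no other of the 114 alternative values changed direction. Among the 0.5 of each list with the stronger scores there were 63052 pairs in MCF7 and 55619 in PANC1, pairs of at least 100 kb were 20.7% and 15.97% (a difference of 4.77 points), 1842 MCF7 pairs were shared (2.34 times the random number), and 12.2% of ranked bins were 4-fold higher in MCF7. Among pairs at least 20 kb apart, 25.6% and 19.1% reached 100 kb (a difference of 6.54 points), and 1401 MCF7 pairs were shared (1.80 times random). Each library's own bins above 500 ends were left out in a setting chosen after the data were seen. The shares of at least 100 kb were then 8.89% and 8.24% (a difference of 0.65 points). The number of shared pairs rested on the definition, from 820 with identical loci to 75341 within 20 kb (1.57 times random), and random shifts of 100 kb to 1 Mb, also chosen afterwards, gave 1.47 times. Bins 4-fold higher in PANC1 were 9.79% with 500 kb bins and 7.26% with 2 Mb bins. Among the named bins, that at 51 Mb of chromosome 11 lost its 4-fold difference with 2 Mb bins (log2 ratio -0.87). The others kept theirs in all settings, of which the 500 kb setting covered only the first 500 kb of each named bin. With pairs at least 20 kb apart, the log2 ratios of chromosomes moved most for 22 (1.69 to 2.50) and 19 (-1.50 to -2.28), and chromosomes 6, 10 and 15 passed 2-fold (-1.11, -1.14 and 1.12). Thinning the MCF7 list left the shared pairs at 2.01 times random. Depth could not be assessed, since the lists hold no reads, and no paired analysis was possible because each cell line had 1 library. Weighting by reads, and the promoter and gene list comparisons with their settings, were not run.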

Other observations

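All tests in this part were chosen after the results they concern had been seen. By overlap of both loci, 0 MCF7 pairs from 1 to 10 Mb apart and 1 over 10 Mb were shared. With the looser limit of 20 kb, a few very long contacts were listed in both cell lines. Of the 271 PANC1 pairs at least 1 Mb apart, 15 had an MCF7 pair within 20 kb at both loci, against 0.02 on average and at most 1 in placements moved by 100 kb to 1 Mb. They fell at 5 places. On chromosome 2, 3 MCF7 pairs and 9 PANC1 pairs joined 163997123-164049451 with 165269059-165361027, 1.29 Mb apart. On chromosome 3, 1 MCF7 pair and 3 PANC1 pairs joined 187457988-187465065 with 188663788-188677385, with scores down to -26.6 in MCF7 and -57.4 in PANC1. On chromosome 7, 2 MCF7 pairs and 1 PANC1 pair joined 83563175-83589564 with 84644547-84658536. The remaining places were on chromosome 5. At the first, 1 pair in each library joined 21556413-21562670 with 29427760-29434223, 7.87 Mb apart.

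The other place on chromosome 5 joined 99384253-99385143 with a locus that began at 134258511 in MCF7 and at 134258553 in PANC1, 34.9 Mb away. This pair ranked 6 by score in PANC1 and 203 in MCF7. The pair was picked because both libraries list it, and its second loci started 42 bases apart. Near-identical sequences or a reference error at the 2 loci are a candidate explanation. A contact between chromosome regions would be expected to spread to neighbouring loci, and 0 other pairs in either library linked positions within 100 kb of both ends. That count does not decide, since most loci in both lists took part in a single pair. At the first place on chromosome 5, MCF7 also had only 1 pair within 100 kb of both ends, and PANC1 had 2. No sequence was examined, and a true contact present in both cell lines stays open.

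The 1 Mb bins with a 4-fold difference between the cell lines lay in blocks. Of the 535 bins, 80.7% lay next to another of the same direction, against at most 56.1% in 100 shufflings of bins within chromosomes. The log2 ratios of bins 5 Mb apart correlated across bins at r = 0.64, against at most 0.38 in the shufflings, which restates that the blocks were long. Unequal template DNA of whole chromosome blocks, from copy number, cannot be told apart from chromatin differences over the same blocks, since no input DNA was analysed here. Each cell line had 1 library, so differences between libraries are not separated from differences between cell lines either.

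The MCF7 pairs at least 2 Mb apart on chromosome 20 had a rate of 10.1 pairs per 1000000 products of bin ends, over bins 3 to 15 Mb apart, and the next highest chromosome, 21, had 1.20, from 1 pair. The region at 61 to 67 Mb of chromosome 3 held 5860 MCF7 ends. On chromosome 20, the regions at 52 to 61 Mb and 44 to 51 Mb held 5135 and 1823. The chromosome 20 rate was 93.1 times that of chromosome 3. Far pairs were thus not in proportion to listed ends. Whether random ligation in proportion to read coverage gave them cannot be decided this way. The lists hold no reads, and the ends come from the same selected pairs. Reads shared between a few short near-identical sequences would involve few loci. The pairs between 52 and 55 Mb involved 99 first and 50 second loci, counted by distinct start, and some of the loci overlapped. Longer stretches of near-identical sequence would also give many loci, so this count does not decide. A rearrangement joining separate blocks is a candidate explanation. The pairs between 52 and 55 Mb ended at position 55854638, and the strongest (score -969) reached this edge. The next strongest, tied at -855, ended short of it, at 55806354, 55839194 and 55847225. Only 1 pair led from the bin at 52 Mb to the bin at 56 Mb, where 180 were expected from the ends in it. That number was scaled from the block with the most pairs and allowed for no decline with distance. A cluster of contacts without a rearrangement could therefore also fall short of it. Long contacts of this cell line without a rearrangement stay open, as the junction itself was not sequenced here.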
